A study of Homo sapiens with 2 samples.

How the data were processed

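Gene expression was measured with Affymetrix exon arrays on total RNA of 2 established human diffuse large B cell lymphoma cell lines, SUDHL6 and HT, with 1 array for each line. An exon array carries probes along the exons of each gene, and the probes of a gene are combined into 1 value per probe set. The labels give the array only as an Affymetrix exon array. Per the labels, both lines were grown in RPMI medium with serum and antibiotics and received no treatment. Biotin-labelled material was hybridised, per the labels. The values are log2 expression values that the authors deposited after RMA, a method that corrects background, normalizes arrays and summarises the probes of each probe set. RMA and the Affymetrix Expression Console are named in the submitters' processing notes. Software versions, the RMA settings, the number of arrays processed together and the genome build are not given in the sources used here.

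The table held 22011 probe sets. Values ran from 0.333 to 13.99 in SUDHL6, with a median of 4.57, and from 0.385 to 13.97 in HT, with a median of 4.58. The sorted columns differed by at most 0.152. RMA is known to compress small differences between dim genes, and no detection call was used here. On 681 probe sets (3.09%) the 2 arrays held exactly the same value.

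Genes were named from the platform annotation of GEO, whose symbols can be old. It listed 16840 of the probe sets, 14432 with 1 gene and 2408 with several. The other 5171 are unnamed here. Symbols were updated through gene numbers to a RefSeq gene table of assembly GRCh38.p14, which matched 14404 of the 14432 probe sets. That table also gave each gene's chromosome and its neighbours. No coordinates are given, because the build behind the probe sets is not stated. Each gene took the probe set with the highest mean where it had several (197 genes), and probe sets naming several genes were left out, which gave 14232 genes with 1 value.

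The level of unexpressed genes was set from 225 olfactory receptor genes, which lymphoma cells were taken not to use. Their 95th percentile, called the dim level here, was 3.81 in SUDHL6 and 4.11 in HT. A gene was counted as different where the log2 difference, SUDHL6 minus HT, was at least 1 either way and the higher value reached the dim level of its line. Folds are 2 to the power of the log2 difference. Where the lower value was below the dim level, the fold was computed against that level and is written as "at least". Levels of different probe sets entered the dim level, the choice of probe sets and named genes, and the matching of random lists. No gene was otherwise described as more highly expressed than another gene. A probe set below the dim level does not show that its gene was silent, since NPM1 and RPS19, which growing cells need, also lay below it in both lines. Nor does a value above it show that a gene was expressed. The level came from 1 gene family, and markers of other cell types, such as GP9 and KLF1, also reached it in both lines. With 1 array per line there is no estimate of the spread between cultures, so no test was made between the lines and no p-value, standard error or replicate check exists.

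The members of 27 gene lists and 8 cell type lists, the thresholds, the rule for named genes and the alternatives were chosen before the data were examined. The median log2 difference of each list, over all members with a value, dim ones included, was placed among the medians of 10000 random lists of the same size, drawn from genes of similar mean level in 20 bins. The resulting percentile describes these 2 arrays. The medians of 22 autosomes and chromosome X were treated the same way, over genes above the dim level. The rule for named genes takes EZH2, EED, SUZ12 and EZH1 always, the 12 genes with the largest difference in each direction, up to 4 members of each list with the largest difference of at least 1, and 3 genes of each chromosome outside the 1st to 99th percentile. A list with no such member named its 2 members with the highest mean level. Immunoglobulin and T cell receptor segments, olfactory receptors, placeholder symbols and genes on Y were left out of the 12. Other genes that are named, such as RBBP4, PHF19, CD74, NPM1 and RPS19, were chosen after their values were seen.

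The procedures were tested on simulated data built from the real values of the 14232 genes. For the count of genes, unchanged genes were drawn from the central spread of each level bin. Of 200 genes changed by 0.5, 1.5 and 3 on the log2 scale, 16%, 85% and 100% were counted as different, and 2.44% to 2.78% of the unchanged genes were. The changed genes were taken from those with a mean at or above the dim level of both lines. The unchanged share is over all other genes, dim ones included. Since the central spread comes from differences between the 2 lines themselves, this share is not a rate of measurement error. Of 100 lists of 15 genes, 4 fell outside the 1st to 99th percentile with no shift, 61 with a shift of 0.3 and 96 with a shift of 0.5. The alternatives tried were centring on the median, quantile normalization, subtraction of a loess curve with a span of 0.3, other treatment of several probe sets per gene, other dim filters, values raised to the dim level, and other random lists. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.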

Results

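Baseline expression was measured in 2 untreated diffuse large B cell lymphoma cell lines, SUDHL6 and HT, as part of work on a small-molecule inhibitor of Polycomb repressive complex 2 (PRC2) that killed lymphoma cells selectively, per the series title. PRC2 places methyl groups on lysine residues of histone H3 and keeps its target genes silent. Each line was represented by 1 array of 22011 probe sets. The precision of every value below is therefore limited by the number of arrays, and no difference could be compared with a spread between replicates. The nearest measure of error was the spread of the differences of 225 olfactory receptor genes. The differences of these 225 genes lay between -1.03 and 1.26 in the central 95%, and 17 of them (7.56%) differed by at least 1 on the log2 scale. Of the 225, 18 reached the dim level in the line with the higher value, 5 of these with a difference of at least 1. The dim level was set from these same genes, so the 18 follow largely from its definition and do not measure error. A difference of 1 is thus close to the noise of dim genes.

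The expression profiles of the 2 lines were alike for most genes and far apart for a small set. Across probe sets, which are not independent replicates, the Pearson correlation was 0.95 and the Spearman correlation 0.939. Of 14232 genes with 1 value, 9405 reached the dim level in the line with the higher value, and 87.7% of these differed by less than 1. SUDHL6 was higher by at least 1 for 498 genes and HT for 657 genes, but this order turned with the scaling, to 576 and 568 after quantile normalization and 584 and 562 after loess. At a difference of at least 2, 167 genes were higher in SUDHL6 and 154 in HT. The other line lay below its dim level for 120 of the 167 and for 102 of the 154, so these genes reached the dim level in 1 line only.

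The genes furthest above HT in SUDHL6 included APOD, S100A10, CD24 and TUBB2B. APOD encodes a lipid-binding apolipoprotein and stood at 11.20 in SUDHL6 and 3.60 in HT, at least 135-fold higher. S100A10, a partner of annexin A2, was at least 48.5-fold higher, at 9.71 against 2.43. CD24, a glycoprotein of the B cell surface, was at least 15.7-fold higher, and TUBB2B, a beta-tubulin, was 64.2-fold higher, at 10.32 against 4.32. The values of CD24 and TUBB2B are uncertain, since both have near-identical copies elsewhere in the genome. The other 8 genes were ZNF711, SMIM14, CHI3L2, TMEM154, PYHIN1, KLHL23, CHPT1 and NELL2, at least 9.49-fold to at least 27.7-fold higher. KLHL23 had another probe set of its own that was at least 4.23-fold higher, and a probe set shared with PHOSPHO2 lay below the dim level in both lines.

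The genes furthest above SUDHL6 in HT included GTSF1, CD9, TCF4 and PTPN13. GTSF1, a germline factor of the piRNA pathway, stood at 10.63 in HT and 2.59 in SUDHL6, at least 112-fold higher. CD9, a tetraspanin of the cell surface, was at least 42.0-fold higher, at 9.20 against 3.51. TCF4, an E protein transcription factor of B cells, was at least 28.0-fold higher, and the phosphatase gene PTPN13 was at least 18.9-fold higher. FGD6, a guanine nucleotide exchange factor gene, was at least 22.9-fold higher, but a probe set it shares with NR2C1 differed by only -0.45. The histone gene H3C3, with at least 19.3-fold, belongs to a family of near-identical copies. ARHGEF6, NCAM2, ACBD7, KIFBP and the desmosomal cadherin genes DSG1 and DSG2 were at least 4.97-fold to at least 14.4-fold higher. In all 12 of these genes the SUDHL6 value lay below the dim level, and so did the HT value of 11 of the 12 genes named for SUDHL6, so the order within each set is not established. Of 5 immunoglobulin and T cell receptor segments with a value, 2 were above the dim level and 1 differed by at least 1.

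**Figure D1:**
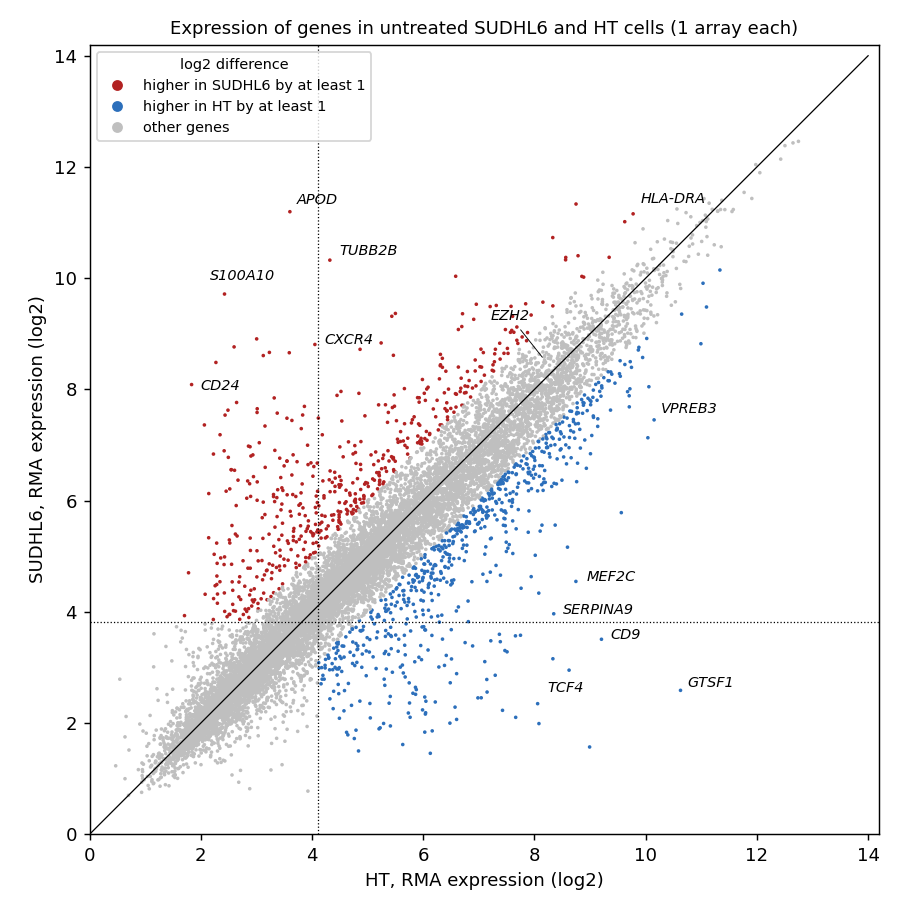
Expression of 14232 genes in HT (x axis) and SUDHL6 (y axis), as log2 RMA values of 1 array each, with the line of equality and each line's dim level dotted. The 498 genes higher in SUDHL6 and the 657 higher in HT by at least 1 are coloured, and APOD and GTSF1 lie far from the line of equality.

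The genes of the PRC2 complex differed by less than 1 between the lines. EZH2, the catalytic subunit, stood at 8.53 in SUDHL6 and 8.18 in HT, a difference of 0.35. EED was at 7.78 and 7.88, SUZ12 at 9.01 and 9.68, and EZH1, the alternative catalytic subunit, at 6.48 and 5.79. Of 11 subunit genes with a value, 9 reached the dim level and 0 differed by at least 1. The accessory subunit gene MTF2 stood at 9.23 and 9.60. The median difference of the list was 0.04, at the 81.3rd percentile of random lists. RBBP4 and PHF19 lay below the dim level in both lines. All these differences were inside the central range of the olfactory receptor genes. Most of those genes were dim, so their range is not an error range for genes at higher levels. The 25th and 75th percentiles of all genes above the dim level were -0.38 and 0.22. EED (-0.11) lay between them, while EZH2, SUZ12 (-0.67) and EZH1 (0.70) lay outside. The arrays measured RNA levels, not protein or sequence.

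**Figure D2:**
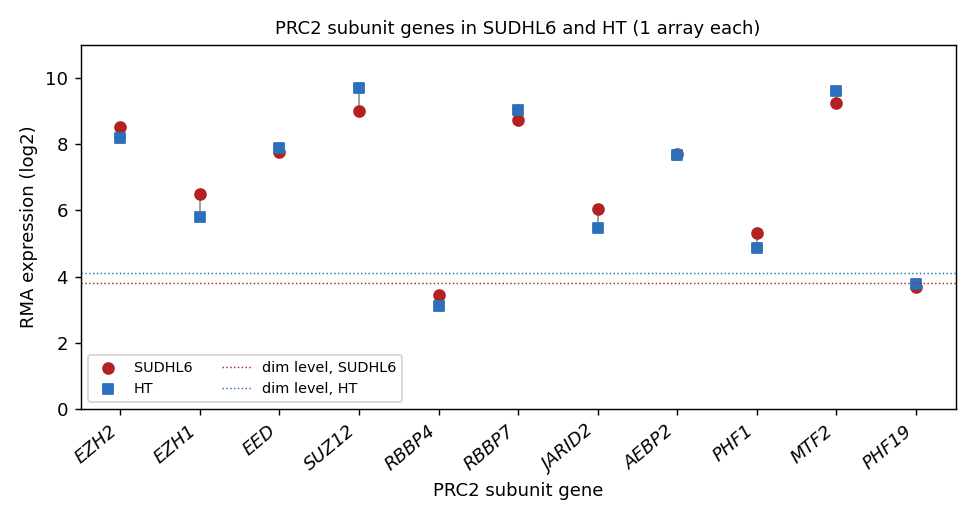
Log2 RMA expression of 11 PRC2 subunit genes in SUDHL6 (circles) and HT (squares), 1 array each, with the dim level of each line dotted. None of the subunits differed by 1 or more, and EZH2 stood at 8.53 and 8.18.

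The other chromatin lists and the classical Polycomb targets gave 0 members with a difference of at least 1. Among 13 PRC1 subunit genes with a value, PCGF6 stood at 8.25 and 8.21 and PHC3 at 7.86 and 7.77 in SUDHL6 and HT, and the median was -0.03 (61.2nd percentile). The list of demethylases and opposing chromatin enzymes had 9 members with a value and a median of -0.17 (39.4th percentile). Within it the methyltransferase genes KMT2A and KMT2C stood at 8.27 and 8.34 in SUDHL6 and 9.07 and 8.08 in HT. The 7 DNA methylation genes had a median of 0.06 (70.9th percentile), with DNMT1 at 7.61 and 7.46 and DNMT3A at 5.43 and 4.89. Of 22 homeobox cluster genes, 6 reached the dim level, with HOXD13 at 4.77 and 4.84 and HOXD9 at 4.60 and 4.81, and the median was 0.00 (60.4th percentile). Of 44 developmental transcription factor genes, 26 reached it, with MSX1 at 5.29 and 5.25 and NEUROG3 at 5.07 and 5.11, and the median was 0.06 (88.6th percentile). Reaching the dim level does not show that these homeobox and developmental genes were expressed.

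Genes of the B cell lists differed in both directions. SERPINA9, a germinal centre B cell marker, was 20.8-fold higher in HT (8.35 against 3.96), and MEF2C, a transcription factor of germinal centre cells, was 18.4-fold higher in HT. GCSAM and CD38 were 3.27-fold and 2.74-fold higher in SUDHL6. Of 17 germinal centre genes above the dim level, 2 were higher in each line and 13 differed by less than 1. The median was -0.04 (71.2nd percentile), or 0.10 after quantile normalization. IRF4, a transcription factor of activated B cells and plasma cells, was at least 5.79-fold higher in SUDHL6, where the kinase gene PIM1 was 5.53-fold higher and BMF 3.49-fold higher. STAT3 was 3.92-fold higher in HT. The activated B cell list had 3 members higher in SUDHL6, 2 in HT (1 with values raised to the dim level) and 9 under 1, with a median of 0.00 (67.0th percentile). In the plasma cell list, IRF4, JCHAIN (3.51-fold) and TNFRSF17 (2.39-fold) were higher in SUDHL6 and SEC11C (3.10-fold) in HT, 8 members were under 1, and the median was -0.16 (26.7th percentile), although the mean was 0.15.

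Among general B cell genes, 25 had a value and all reached the dim level, 5 of them higher in SUDHL6 and 4 in HT. CD24 and the transcriptional repressor gene BACH2, at least 7.37-fold, were higher in SUDHL6. The complement receptor gene CR2, at least 4.14-fold, and VPREB3, 6.50-fold, were higher in HT. The median was -0.10 (50.04th percentile) and the mean 0.21. In the list of B cell receptor and PI3K signalling, the kinase gene FYN was 7.99-fold higher in HT, the phosphatase gene PTPN6 3.73-fold higher in HT, and PRKCB, a protein kinase C gene, at least 3.54-fold higher in SUDHL6. The other 16 members above the dim level differed by less than 1, and the median was -0.16 (39.1st percentile). REL, an NF-kB subunit gene, was higher in SUDHL6, at 8.63 against 6.31, and so was CD83 (4.65-fold), while CFLAR, an inhibitor of caspase-8, was at least 2.34-fold higher in HT. The NF-kB list had 13 further members under 1 and a median of 0.06 (86.7th percentile).

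Genes of apoptosis differed in both directions. In the BCL2 family, BCL2, which opposes cell death, was at least 2.17-fold higher in SUDHL6, together with the pro-apoptotic genes BMF (3.49-fold) and PMAIP1 (2.24-fold). BCL2L2, another anti-apoptotic member, was 3.22-fold higher in HT. The other 8 members above the dim level were under 1, and the median was 0.20 (97.3rd percentile), or -0.0055 with probe sets naming several genes included. In the extrinsic apoptosis and caspase list, CASP6, an effector caspase gene, was at least 4.41-fold and CFLAR at least 2.34-fold higher in HT. Of its 16 members, 14 had a lower value in SUDHL6 than in HT, death-promoting and inhibitory genes alike, although 12 of the members above the dim level differed by less than 1. The median was -0.43, at the 0.11th percentile of random lists, or at the 1.89th after the median of each gene's neighbours was subtracted. This was 1 of 3 lists of 35 outside the 1st to 99th percentile, where chance alone gives 0.7, and of 2 when random lists were matched on the higher value.

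The growth and cell cycle lists and the 9p21 neighbours lay between the 22nd and the 79.3rd percentile of the random lists. Of 27 proliferation genes, RRM2 (2.62-fold) and MCM3 (2.18-fold) were higher in SUDHL6 and CDC20 (2.64-fold) and CDK1 (2.14-fold) in HT, 23 were under 1, and the median was -0.12 (57.0th percentile), or 0.053 with probe sets naming several genes included. GADD45A, a stress-induced growth arrest gene, was 3.56-fold higher in SUDHL6. The other 7 cell cycle inhibitors were under 1, and the median was -0.16 (22nd percentile), with a mean of 0.06. In the MYC and ribosome biogenesis list, POLR1B was 2.05-fold higher in SUDHL6, 10 members were under 1, and the median was -0.18 (26.7th percentile). Among cytosolic ribosomal proteins, which have many pseudogene copies, RPL8 (2.03-fold) and RPS13 (at least 1.91-fold, under a difference of 1 with values raised to the dim level) were higher in HT, 10 members were under 1 and the median was -0.12 (46.8th percentile). The 9p21 neighbours, 3 of 7 above the dim level, had KLHL9 at 5.07 and 5.67 and CDKN2B at 4.80 and 5.10, with a median of 0.09 (79.3rd percentile), or -0.30 over the 3.

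Of the class II antigen presentation genes with a value of their own, 4 HLA genes were higher in SUDHL6 by at least 1. HLA-DMB was 8.88-fold, HLA-DPB1 5.11-fold, HLA-DRA 2.61-fold and HLA-DPA1 2.19-fold higher, and 0 members were higher in HT by at least 1. The other 6 members were under 1, among them the invariant chain gene CD74, at 9.96 and 10.07. The median was 0.36 (99.5th percentile of random lists, and the 98.9th when these were matched on the higher value), or 0.21 with probe sets naming several genes included. After the median of each gene's neighbours was subtracted, the list was at the 96.9th percentile. A probe set shared by HLA-DMA and HLA-DMB differed by only 0.23, and 2 probe sets shared by the HLA-DRB genes were at least 2.72-fold and at least 5.05-fold higher in HT. The 30 nearest neighbours of the HLA class II genes had a median of 0.39. In the class I list, the peptidase gene ERAP2 (2.78-fold) and HLA-E (2.02-fold) were higher in SUDHL6 and the immunoproteasome gene PSMB8 (2.46-fold) and CALR (2.23-fold) in HT, 8 members were under 1, and the median was 0.16 (95.3rd percentile). It was -0.07 (40.6th percentile) after the median of each gene's neighbours was subtracted. HLA genes vary in sequence, and the probes were not checked for this.

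Interferon-induced genes split between the lines. IFIH1, a sensor of double-stranded RNA, was at least 4.51-fold higher in HT, where IFIT3 and IFIT5 were at least 1.78-fold and 1.75-fold higher. MX2, an antiviral GTPase, was at least 4.23-fold higher in SUDHL6. Of 24 members with a value, 14 reached the dim level, 2 higher in SUDHL6, 3 in HT and 9 under 1. With values raised to the dim level, 1 was higher in SUDHL6 (MX2) and 1 in HT (IFIH1). The median was -0.02 (41.4th percentile).

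Metabolic, stress and surface genes also held single large differences. In the endoplasmic reticulum stress and amino acid list, the serine synthesis gene PHGDH (2.96-fold) and the lipoprotein receptor gene VLDLR (at least 1.75-fold, likewise under a difference of 1 with values raised) were higher in SUDHL6, while HSPA5, the main chaperone of the endoplasmic reticulum, was 2.32-fold higher in HT. The other 13 members were under 1, and the median was 0.33 (99.9th percentile), or 0.22 with values raised to the dim level. Of the 16 members, 10 had a higher value in SUDHL6 and 6 a lower one, HSPA5 and ATF4 among the 6. ATP5MC1, an ATP synthase gene, was 2.74-fold higher in HT, 18 other oxidative phosphorylation genes were under 1, and the median was -0.29 (9.40th percentile). Cholesterol synthesis genes had 0 members with a difference of at least 1, with SQLE at 9.33 and 8.93, HMGCS1 at 8.44 and 8.27 and a median of 0.01 (78.0th percentile). CXCR4, a chemokine receptor, was at least 25.9-fold higher in SUDHL6, as was the integrin gene ITGAL (2.5-fold), whereas CD9 and the integrin gene ITGB1 (13.4-fold) were higher in HT. The adhesion and migration list had 7 members under 1 and a median of 0.10 (93.3rd percentile), with a mean of -0.10. With values raised to the dim level its median was -0.30, the value that raising gives by construction to a gene dim in both lines. Of 12 drug efflux and metabolism genes, 4 reached the dim level. Among these, the transporter gene ABCC4 was 2.57-fold higher in SUDHL6 and GSTP1 2.04-fold higher in HT. The median over all 12, most of them dim, was 0.17 (96.8th percentile), or the same -0.30 by construction with values raised to the dim level.

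Markers of other cell types were mostly below the dim level, and 7 of the 8 marker lists had 0 members with a difference of at least 1, the exception being the fibroblast and endothelial list. T cell markers CD7 (5.49 and 5.73) and CD8A (4.40 and 4.25), NK cell markers NKG7 (4.91 and 5.30) and GNLY (4.26 and 3.81) and myeloid markers CD68 (5.53 and 5.95) and TYROBP (4.27 and 4.08) differed by less than 1 between SUDHL6 and HT. So did GP9 (4.98 and 5.05), KLF1 (5.09 and 4.61), KRT8 (8.27 and 8.12), KRT14 (5.42 and 6.11), SYN1 (4.39 and 4.32) and STMN2 (3.98 and 3.54). Of 10 epithelial genes with a value, 4 reached the dim level, KRT8 among them, while KRT18 lay below it in both lines (3.56 and 3.85). The precursor B cell list, also with 0, had MME at 8.89 and 8.39 and SOX4 at 5.10 and 4.80. The extracellular matrix genes LUM and DCN, neighbours on chromosome 12, were at least 5.29-fold and 2.35-fold higher in HT. The median of their list was 0.01 (57.4th percentile) over 12 members and -1.51 over the 4 above the dim level. The median was -0.02 (41.8th percentile) for T cell, 0.12 (87.6th, and -0.25 with probe sets naming several genes included) for NK cell, 0.04 (71.9th) for myeloid and 0.00 (53.3rd) for erythroid and platelet markers. It was -0.02 (49.98th) for epithelial, -0.05 (33.9th) for neuron and 0.05 (77.0th) for precursor B cell markers.

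**Figure D3:**
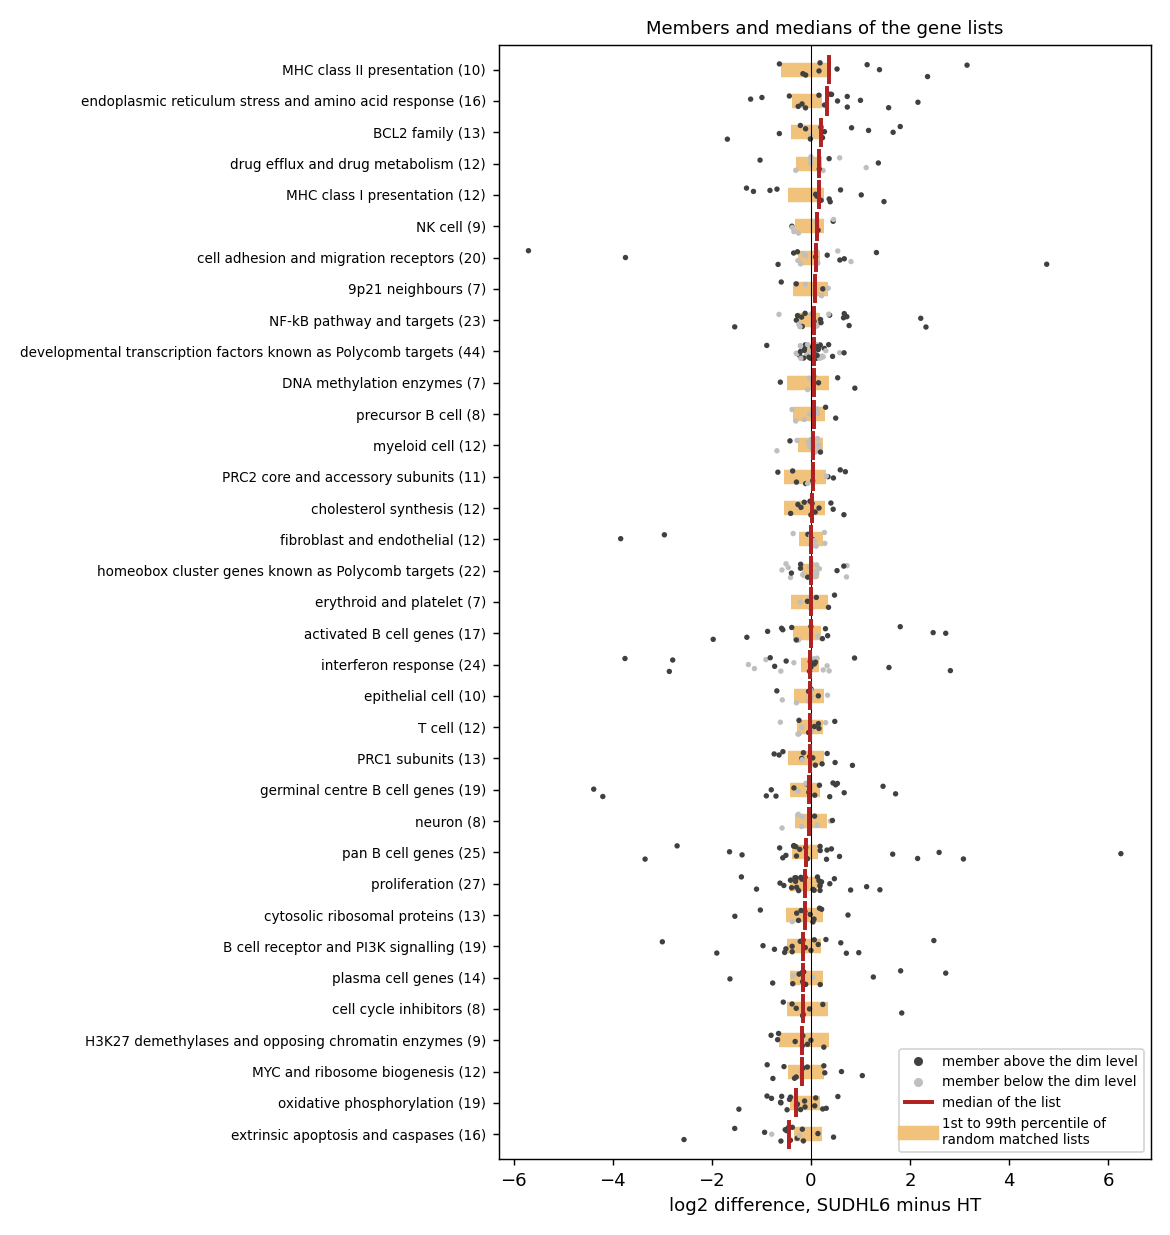
Log2 differences (SUDHL6 minus HT) of the members of 35 gene and cell type lists, each point 1 gene of 1 array per line, with the list's median as a bar and the 1st to 99th percentile of random matched lists as a band. The number of members with a value is in brackets, and the class II, endoplasmic reticulum stress and extrinsic apoptosis lists have medians of 0.36, 0.33 and -0.43 outside their bands.

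Differences between the lines were not spread evenly over the chromosomes. Over 9394 genes above the dim level the median difference was -0.05 and 44.5% of genes were higher in SUDHL6. Chromosome 6 had a median of 0.26, with 65.8% of 488 genes higher in SUDHL6, chromosome 2 one of 0.13 and chromosome 7 one of 0.12, each above all random lists, and chromosome 1 had a median of 0.00 (99.8th percentile). Chromosomes 10, 15 and 14 had medians of -0.27, -0.22 and -0.20, below all random lists. Chromosomes 12, 22, 17 and 19 followed with medians of -0.15, -0.14, -0.11 and -0.06, each below the 1st percentile. The genes with the largest differences in these directions were CD24, TUBB2B and the cannabinoid receptor gene CNR1 (at least 6.88-fold) on chromosome 6, KLHL23, KYNU (at least 8.40-fold) and CXCR4 on chromosome 2, and LRRN3 (at least 23.3-fold), TES (at least 7.23-fold) and ELAPOR2 (at least 5.43-fold) on chromosome 7. They were S100A10, CHI3L2 and PYHIN1 on chromosome 1. Among genes higher in HT they were ACBD7, KIFBP and the proteoglycan gene SRGN (13.7-fold) on chromosome 10, the last 2 of which lie in a run of 15 neighbours lower in SUDHL6, SERPINA9, SYNJ2BP (at least 3.86-fold) and GNG2 (10.8-fold) on chromosome 14, and DNAJA4 (at least 4.10-fold), TEX9 (5.56-fold) and the cathepsin gene CTSH (5.49-fold) on chromosome 15. On chromosome 12 they were GTSF1, CD9 and FGD6, on chromosome 17 GAS7 (at least 14.4-fold), CEP112 (at least 3.53-fold) and ZFP3 (at least 1.93-fold), on chromosome 19 the zinc finger genes ZNF256, ZNF175 and ZNF613 (at least 3.82-fold to at least 4.64-fold), and on chromosome 22 SMC1B (at least 6.35-fold), RBFOX2 (9.91-fold) and VPREB3. The percentiles treat genes as independent draws.

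**Figure D4:**
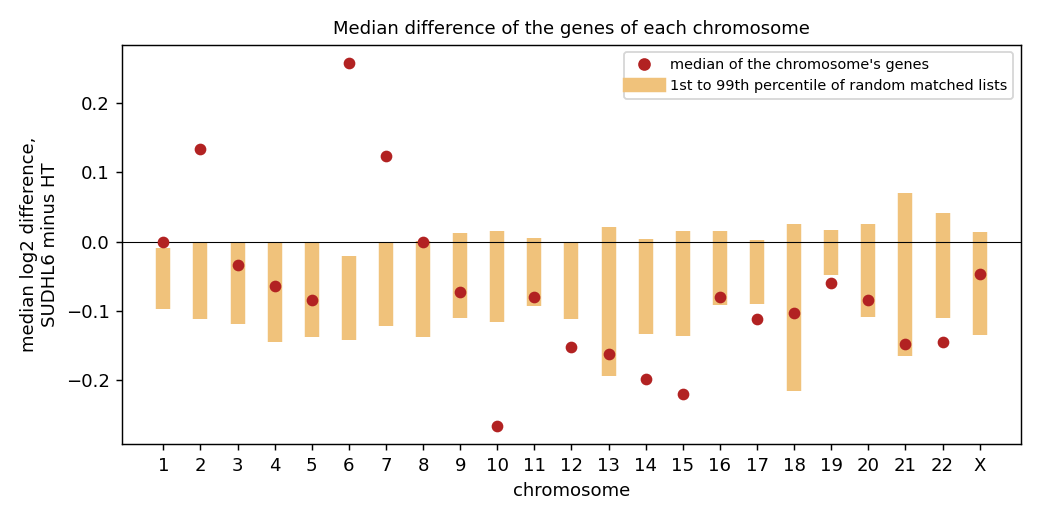
Median log2 difference (SUDHL6 minus HT, y axis) of the genes above the dim level on each chromosome (x axis), from 1 array per line, with the 1st to 99th percentile of random matched lists as bands. Chromosome 6, at 0.26, and chromosome 10, at -0.27, lie furthest from their bands.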

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

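Of this part, only the counts of list members with values raised to the dim level and the shift common to all chromosomes were chosen after the results were seen. The counts of genes with a difference of at least 1 or 2 stayed within 1.5 times under all 9 alternatives. The number with a difference of at least 1 ran from 1004 to 1400, and the share of them higher in SUDHL6 from 40.7% to 51.0%, with 576 higher in SUDHL6 and 568 in HT after quantile normalization. Of 786 alternative values of 131 named genes, 736 moved by less than 0.431, the robust SD of the olfactory receptor differences, and 47 of the other 50 came from raising values to the dim level. Named genes with a difference of at least 1 kept their sign under the 6 alternatives run on them. Quantile normalization and loess each turned the sign of 4 list medians near 0 (PRC1, germinal centre, general B cell and interferon) and of EED, loess that of NEUROG3, and quantile normalization that of the medians of chromosomes 3 and X. The number of chromosomes outside the 1st to 99th percentile was 11 in the main result, 11 after quantile normalization and 12 with trimmed means, but 22 of the 23 medians moved by more than the SD of their random lists under quantile normalization, which shifted all placed genes together by 0.051, and 2 of 23 did once that shift was taken off, while 11 moved with trimmed means. Medians of lists were judged against the SD of their random lists. Raising values to the dim level, which by construction gives -0.30 to a gene dim in both lines, moved the homeobox, activated B cell, interferon, adhesion, drug, 9p21, NK cell, myeloid, epithelial, fibroblast, neuron and precursor medians to -0.30, the T cell median to -0.29 and the developmental factor and NF-kB medians to -0.17. With members above the dim level alone, the medians were -0.14 for homeobox, -0.15 for activated B cell, 0.20 for NF-kB, -0.30 for 9p21, 0.11 for T cell, -0.12 for myeloid, 0.23 for erythroid, -1.51 for fibroblast, 0.25 for neuron and 0.40 for precursor genes. With probe sets naming several genes, they were 0.14 for activated B cell, -0.0055 for BCL2 family, 0.053 for proliferation and -0.25 for NK cell genes. Quantile normalization put the germinal centre median at 0.10 and loess the general B cell median at 0.024. The class II list went from the 99.5th to the 98.9th percentile with random lists matched on the higher value. The cause was not tested for the values of these last 4 sentences. Raising values also lowered the number of members with a difference of at least 1 in the activated B cell, interferon, ribosomal protein and endoplasmic reticulum stress lists, but in no other list. The extrinsic apoptosis and endoplasmic reticulum stress lists stayed outside the 1st to 99th percentile with both other kinds of random lists. No paired analysis was possible because each line had 1 array, and signal near background limits all folds written as a lower bound.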

Other observations

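The count of adjacent pairs, the window scan with values raised to the dim level and the tests of chance order of genes, of single chromosome runs and of sequence variants under the HLA probes were chosen only after the results were seen, as were the genes and regions named in this part.

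Some adjacent genes outside the fixed lists, picked because both differed, did so in the same direction. PYHIN1, IFI16 and AIM2, neighbouring genes of DNA-sensing proteins on chromosome 1, were all higher in SUDHL6, IFI16 5.97-fold, AIM2 14.7-fold and PYHIN1 at least 23.4-fold, and so were the Fc receptor-like genes FCRL3 (at least 13.3-fold) and FCRL2 (4.29-fold) and the fatty acid desaturase genes FADS1 (4.14-fold) and FADS2 (at least 3.11-fold). PARP9, DTX3L and PARP14, neighbours on chromosome 3 that are known to respond to interferon, were higher in HT, at least 4.13-fold, 2.34-fold and 5.53-fold. SMC1B, a meiotic cohesin subunit, was at least 6.35-fold higher in HT. TXNIP, an inhibitor of thioredoxin, was 4.54-fold higher in SUDHL6. Over the genome there were 23 pairs of adjacent genes that both differed by at least 2 in the same direction, against a median of 5 and a highest value of 15 in 1000 shuffles of the genes among those of similar level. Adjacent here means consecutive among the 9394 genes above the dim level. Pairs of related genes were not taken out, and a gene with such a partner on each side entered 2 pairs. Of the 23 pairs, 4 lay inside the runs described next.

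Longer runs were found in windows of 15 adjacent genes above the dim level. The chromosome 11 run spanned 34 genes from DCUN1D5 to APOA5, with a median of -1.42 and 26 genes lower in SUDHL6 by at least 1, among them IL18 (at least 6.77-fold), SDHD (at least 2.03-fold), PPP2R1B (4.27-fold), DLAT (3.34-fold) and the B cell coactivator gene POU2AF1 (2.62-fold). With values raised to the dim level its median was -1.40. The chromosome 10 run spanned 15 genes from SIRT1 to SUPV3L1, with a median of -1.28 and all 15 lower in SUDHL6, including KIFBP and SRGN. On chromosome 6, 15 genes from SLC35B3 to MYLIP had a median of 1.03 and included CD83. On chromosome 12, 18 genes from FOXJ2 to CREBL2 had a median of -0.99, or -0.76 with values raised to the dim level, with the families of CLEC and TAS2R genes among them. On simulated orders of the 9394 genes with a run of 30 genes lowered by 1, a window lay below all shuffles in 96% of 50 draws. With a run lowered by 0.5 this was so in 4%, and with no lowering in 2%. The window was not required to lie in the run. All draws were set against the same 100 shuffles, a looser criterion than the 1000 used for the scan.

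Runs of neighbouring genes differed the same way. The lowest window median was -1.95, on chromosome 11, where the lowest of 1000 shuffles was -1.22, so chance order of genes is argued against. The lowest median was also beyond its shuffles after a loess curve was subtracted (-1.87 against -1.003) and with values raised to the dim level (-1.60 against -1.03). This argues against scaling as the whole cause there. Of genes on a chromosome whose symbols start with the same 3 letters, 1 was then kept, and the lowest median was still beyond its shuffles (-1.74 against -1.06). This argues against families of like-named genes as the whole cause there. Probe sequences were not compared, so shared probes were not tested. The highest median, on chromosome 6, was 1.03 against 1.01 in the shuffles (0.92 with raised values). After loess and with 1 gene per such set, the highest lay on chromosome 2, within the shuffles (1.11 against 1.33 and 1.09 against 1.14). Genes left out of the scan had a median shift in the region's direction of 0.59 over the 3 regions that had any (16 probe sets), and of 0.84 on chromosome 11, but of 0.36 on chromosome 6 (3 probe sets) and of -0.80 on chromosome 12 (4 probe sets), so a difference over the whole region is consistent with the chromosome 11 run, while chromosomes 6 and 12 stay open and chromosome 10 had no such genes. DNA copy number and regional chromatin cannot be told apart from RNA alone.

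The class II list stood out through its 5 HLA genes, whose median was 1.38, while their 30 nearest neighbours outside the list had a median of 0.39, with 26 of 30 higher in SUDHL6. The HLA genes lay 0.99 above these neighbours, just under the bound of 1 set beforehand, so a shift of the region may account for part of the difference and cannot be told apart from a change in the HLA genes themselves. The 5 members outside the HLA family had a median of -0.11, at the 55.5th percentile, and the HLA-DRB probe sets went the other way, which is consistent with sequence variants under the probes. Against variants as the whole cause stands HLA-DRA, a gene known to vary little, which was 1.38 higher.

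The extrinsic apoptosis list was lower in SUDHL6 with a median of -0.43. When the median of each gene's 14 nearest neighbours was subtracted from every gene, the list's median was -0.28, at the 1.89th percentile, with an SD of random lists of 0.131. This percentile lies within the 1st to 99th, the outcome set beforehand for shifts of chromosome regions as the cause. Such shifts may therefore account for part of the difference, although most of the median remained. The list's percentile was 0.11, and its exact 95% binomial interval for the 10000 random lists, from 0.055 to 0.197, spanned the 0.148 that the lowest of 35 independent lists falls below in 5% of draws. Against chance stand the 3 lists outside the 1st to 99th percentile, where the 95th percentile of draws was 2 and 3.21% gave as many, and a lowest list as low in 3.78% of draws. These draws took the lists as independent, although some share members, such as CFLAR in this list and the NF-kB list. The class II list, 1 of the 3, stood out through HLA genes of 1 chromosome region. The interval also spanned the bound, and 2 lists were outside when random lists were matched on the higher value. Chance among the lists examined is therefore not excluded.

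After the same subtraction the endoplasmic reticulum stress list was at the 99.2nd percentile, the class II list at the 96.9th, and the NF-kB and NK cell lists at the 99.9th and 99.3rd. The class I list went from the 95.3rd to the 40.6th percentile. The interferon and oxidative phosphorylation lists fell to the 2.27th and 1.79th. The neighbours' median was also taken off dim members, which may not show such a shift. Only 3 of 9 NK cell members were above the dim level, and NCAM1 lies inside the chromosome 11 run. The NK cell percentile may therefore come from the shifts of neighbours. Exactly equal values on both arrays were held by 188 of the 9405 genes above the dim level and by 353 of the 4827 below it. The olfactory receptor gene OR13A1, 1 of the 225 genes that set the dim level, was at least 6.60-fold higher in SUDHL6, and its neighbour ALOX5 at least 4.15-fold higher. The assumption that lymphoma cells do not use these genes may therefore not hold for OR13A1.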
